A study of Aspergillus nidulans with 8 samples.

How the data were processed

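RNA of 2 strains of the filamentous fungus Aspergillus nidulans was compared on 8 two-colour Agilent arrays, 2 for each of 4 growth conditions. The conditions were minimal medium with 4% glucose, or with 2% glycerol and 100 mM threonine, each for 16 h or 24 h at 37 °C. On every array the control strain, Wt, was labelled with Cy3 and the strain alcAypkA with Cy5, per the labels of the channels. The labelling protocol in the labels holds wording about other samples, so the direction of each ratio was taken from the channel labels alone. Both arrays of a condition are biological replicates per the labels, which do not describe the cultures further, so p-values measure the spread between these samples.

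The deposited scanner tables give the mean intensity and the median background intensity of each spot in both channels, with marks for spots well above background, saturated spots and outlier spots. They were made with Agilent Feature Extraction 9.5.3.1 under the protocol GE2-v5_95_Feb07, per the file headers. The deposited tables also hold processed signals, which Feature Extraction background-corrected and dye-normalised and which were used as an alternative. The deposited series table holds log10 ratios of Cy5 over Cy3. Its values were set against the scanner's own log10 ratio of the same spot, and 100% matched within 0.6%, so its scale and direction are known. The deposited column of glucose 16 h replicate 1 was a score, the same log10 ratio without its decimal point, and was divided by 1e9. The median of each deposited column was 0. Every column of sample values was used, and 0 were left aside.

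Each array holds 43803 spots. The 11143 probes that are not controls stand for 1 gene each, so no choice between probes of a gene was needed. Gene names come from a reference table of the assembly ASM1142v1, which served for names and for the order of genes along chromosomes. Of the 11143 identifiers 10443 matched it, and 774 of them have a symbol there. No coordinates are given, since the array tables name no genome build. Many symbols of the table follow homologues in other Aspergillus species. Genes without a symbol are called by their AN identifier, and for members of gene lists the symbol under which they were entered is given as such. ypkA was entered as AN5973. The same sequence is shared by 131 probes in all, 114 of them among the genes kept, and none of the genes named in the text.

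Intensities were background-corrected with normexp (offset 50) and normalised by loess within each array in limma 3.58.1 under R 4.3.3, with statmod 1.5.0 and the data.table package, version 1.17.8. Control spots and outlier spots had weight 0 in the loess and were then left out; a probe with outlier spots alone on an array kept their mean. Spots of a probe were averaged. A gene was kept if its probe was well above background in at least 1 channel on at least 2 of the 8 arrays, which left 8996 genes and removed 2147. Limma's lmFit and eBayes were fitted to the log2 ratios with 1 mean per condition, 4 residual degrees of freedom and 3.21 prior degrees of freedom. P-values were adjusted with the Benjamini-Hochberg method over all genes kept, and a gene was called at adjusted p under 0.05. In comparisons of strains "rose" means higher in alcAypkA than in Wt. Comparisons within Wt used limma's separate-channel fit (Aquantile between arrays, intraspot correlation 0.14). Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15 and pandas 2.3.3.

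The dyes were not swapped, so an effect of the dye on a probe cannot be told from an effect of the strain within a condition. Such an effect cancels in differences between media and between times. The slide numbers in the names of the deposited files place the arrays on 2 slides, each with 1 medium, while the barcodes in the scanner headers of the threonine arrays repeat those of the glucose arrays. The former were followed, so slide and medium cannot be told apart if they are right, and the fit to the arrays of 1 medium is then the fit within a slide.

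A probe not well above background in a strain on every array of a condition, or saturated there, has only a bound. The bound is the brighter strain's mean normalised level against the dimmer strain's mean of, per array, the higher of its own level and the lowest level among probes well above background. Saturated spots entered at their value. These bounds compare both channels and are open to dye bias.

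Genes named in the text follow a rule set before the data were examined. In each main comparison it takes ypkA, the 8 highest and 8 lowest log2 values among called genes that have a symbol or description and the same sign on every array (no overlap of arrays for differences), and up to 4 called members of each gene list with the smallest p. In the other comparisons it takes the 3 highest and 3 lowest. AN8979 and AN0554 were followed condition by condition after their values were seen. Of 26 planned gene lists 15 had at least 5 members on the array. Lists defined by descriptive words found none, since the reference table gives symbols alone. Other planned lists had 1 to 4 members. Entries were dropped where the table gave the identifier another symbol, which held for 29 identifiers. Among these were catB and sodA of oxidative stress defence, a list left with 2 members. A further 13 lists were written from the table's symbols before any expression value was seen. Lists with at least 5 genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera's estimated correlation and fry as companions, adjusted over the 28 lists of a comparison. The plan named the main comparisons for them, and the other comparisons were added to it. The planned lists, the tests and most alternatives were fixed before the data were examined.

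The fits and the list test were tried on simulated data. Values were drawn as normal noise with the spread of each gene, independent between genes, and known changes were added. Background correction, loess, averaging of spots and the filter were not run on them. The shares and false calls below therefore hold for the fits under such noise and do not give the rate of false calls in the real data. In the simulated glucose comparison 53.7% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 8 false calls among 8996 genes. For threonine minus glucose the shares were 13.4%, 82.1% and 98.5%. For 24 h minus 16 h in glucose they were 0%, 28.4% and 95.5%, and for Wt threonine minus glucose 52.2%, 95.5% and 100%. A simulated list shifted by 0.5 on the log2 scale in the glucose comparison was called in 100 of 100 draws, and unshifted lists in 7 of 2700. These rates belong to the simulated lists alone: of the camera calls in the real lists 0 held with an estimated correlation.

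The alternatives were no background correction, Agilent's processed signals, the deposited log10 ratios, median centring in place of loess, scale normalisation between arrays, a stricter filter, no filter, a 2-fold minimum, a trended and robust eBayes, a fit to 1 medium alone, the replicate number as a block, each array left out in turn and, for Wt, the Cy3 channel alone or quantile normalisation of all channels. Their effect is given in the closing section. Taking the brightest probe per gene was planned and not run, because each gene has 1 probe.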

Results

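Expression was measured in Aspergillus nidulans strains Wt and alcAypkA, hybridised together on 8 two-colour arrays. The series compares Wt with a strain in which ypkA is induced or repressed. ypkA (AN5973) encodes a protein kinase related to the yeast Ypk kinases and mammalian SGK, and the alcA promoter is repressed by glucose and induced by threonine. Cultures grew for 16 h or 24 h in glucose, or in glycerol with threonine (called threonine here), with 2 arrays in each of the 4 conditions. The share of spots well above background was 68.5 to 78.7% in the Wt channel and 59.4 to 77.2% in the alcAypkA channel. The alcAypkA channel was dimmest on replicate 1 of glucose 24 h (median intensity 80.6, 60.5% of spots above background) and replicate 1 of threonine 24 h (145, 59.4%), against medians of 165 to 268 on the other arrays. Replicate arrays correlated across genes at 0.80 for glucose 16 h, 0.71 for glucose 24 h, 0.85 for threonine 16 h and 0.83 for threonine 24 h. The number of arrays limits the precision of every value.

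The targeted gene was lower in alcAypkA than in Wt in glucose at both times, higher in threonine at 16 h, and lower on the arrays labelled threonine 24 h. In glucose the log2 ratio of ypkA (AN5973) was -1.79 and -1.89 at 16 h and -1.17 and -2.02 at 24 h. In threonine it was 1.40 and 1.67 at 16 h, and -1.01 and -1.25 on the arrays labelled threonine 24 h. The mean over the glucose arrays was -1.72 ± 0.14 (SE, n = 4 arrays, limma adjusted p = 0.00030), and lower in 4 of 4 arrays. Threonine 16 h gave 1.54 ± 0.20 (adjusted p = 0.0058) and threonine 24 h -1.13 ± 0.20 (adjusted p = 0.0069), so the mean over the threonine arrays was 0.20 ± 0.14 and was not called (adjusted p = 0.36). The ratio changed by -2.66 ± 0.29 from 16 h to 24 h in threonine (adjusted p = 0.0017) and by 0.24 ± 0.29 in glucose (adjusted p = 0.60). It was higher in threonine than in glucose by 1.92 ± 0.20 (adjusted p = 0.0013). In Wt the gene did not pass the test between media (-0.26 ± 0.13, adjusted p = 0.13). Because ypkA goes against an induced promoter there, the arrays labelled threonine 24 h are named by their label wherever a direction rests on them. The gene was not well above background in alcAypkA on replicate 1 of both 24 h conditions, and Agilent's processed signals gave -3.13 in glucose.

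**Figure D1:**
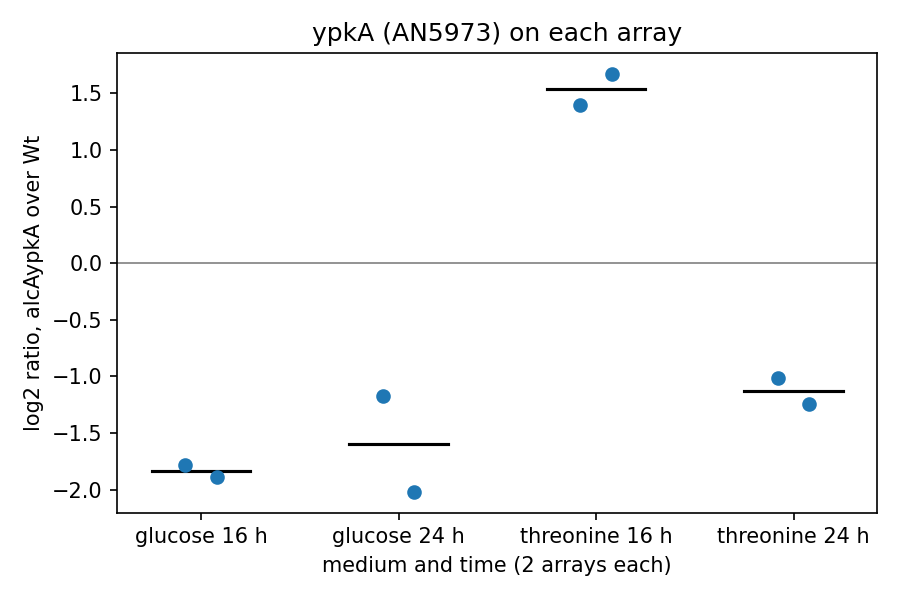
Log2 ratio of ypkA (AN5973), alcAypkA over Wt, on each array (points) with the mean of each condition (lines), by medium and time. The 4 glucose arrays lie between -2.02 and -1.17, the threonine 16 h arrays at 1.40 and 1.67, and the arrays labelled threonine 24 h at -1.25 and -1.01.

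In Wt, the change from glucose to threonine raised most genes of ethanol use together with genes of an orsellinic acid cluster, and lowered genes of nitrogen uptake and breakdown. This comparison gives the setting of the strain effects, and it includes the Wt channel of the arrays labelled threonine 24 h, whose values would change if their channels were exchanged. AN8979, entered as alcA (alcohol dehydrogenase), rose by 4.77 ± 0.28 (SE, limma separate-channel adjusted p = 5.4e-07) and AN0554, entered as aldA (aldehyde dehydrogenase), by 3.0 ± 0.18. Of 10 measured members of the alc regulon 7 rose and 3 were not called (7 adjusted over the list alone), and AN8981, entered as alcS, rose by 3.72. The list counts creA and creB along with the alc genes, and its member AN2286, entered as alcC, had saturated spots. Camera called the list (adjusted p = 0.00010, and adjusted p = 0.45 with an estimated correlation). Among other secondary metabolite clusters 13 of 20 members rose and 4 fell, the same numbers as adjusted over the list alone (camera adjusted p = 0.0044, and adjusted p = 0.63 with an estimated correlation). They include AN7914 (4.41), AN7909 (3.92), AN7911 (3.43) and AN7912 (3.06), entered as genes of the orsellinic acid cluster.

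Genes of nitrogen and amino acid breakdown went the other way in Wt, where 12 of 15 fell in threonine and 3 were not called (14 fell and 1 rose adjusted over the list alone). gatA, a GABA transaminase, changed by -2.75, the proline genes' member prnD by -2.19 and the nitrate transporter crnA by -2.04 (camera adjusted p = 0.00010, and adjusted p = 0.63 with an estimated correlation). Ribosome biogenesis genes rose in 18 of 25 cases (20 adjusted over the list alone), such as has1 (0.82) and loc1 (1.14), with camera adjusted p = 1.9e-06 and adjusted p = 0.63 with an estimated correlation. Of 13 ribosomal protein and translation genes 9 rose (10 adjusted over the list alone), with rps1 at 0.97 and rps21 at 0.69 (camera adjusted p = 0.0019, and adjusted p = 0.63 with an estimated correlation). In the list of amino acid synthesis 16 of 23 rose and 1 fell (17 and 2 adjusted over the list alone, camera adjusted p = 5.8e-05, and adjusted p = 0.50 with an estimated correlation). Among single genes sC, ATP sulfurylase of sulfate assimilation, rose by 1.37, pksP of the spore pigment by 1.69, the conidiophore pigment gene ivoB by 2.23 and the spore hydrophobin dewA by 2.80, though dewA was well above background on 1 of 4 glucose arrays. thiA of thiamine synthesis changed by -4.06 ± 0.23, with the Wt spot saturated on 1 of 4 glucose arrays. In all 3707 of 8996 genes were called, 1912 higher and 1795 lower in threonine. Slide and medium cannot be told apart here if each slide holds 1 medium, and the count was 2350 without threonine 16 h replicate 2.

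Between 16 h and 24 h in Wt, averaged over both media and with the Wt channel of the arrays labelled threonine 24 h included, part of the chaperone genes rose and part of the ribosome biogenesis genes fell. hsp78, a mitochondrial chaperone, rose by 1.94 ± 0.26 (SE, adjusted p = 0.00058), admA by 2.18 ± 0.09 and osm1 by 1.89 ± 0.26. catA, a spore catalase, changed by -0.87, lysF of lysine synthesis by -0.83 and mde1 by -0.73. Of 15 members of the list of chaperones and unfolded protein response 9 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00045, and adjusted p = 0.48 with an estimated correlation). Of 25 ribosome biogenesis genes 13 fell (17 adjusted over the list alone, camera adjusted p = 2.3e-05, and adjusted p = 0.50 with an estimated correlation). The sterigmatocystin cluster had 8 of 14 members that rose (9 adjusted over the list alone, camera adjusted p = 0.00039, and adjusted p = 0.48 with an estimated correlation). The comparison called 2360 genes, 1110 higher and 1250 lower at 24 h, and at a 2-fold minimum 373, 306 higher and 67 lower. The count ranged from 936 without threonine 16 h replicate 2 to 2981 without glucose 24 h replicate 1, and the Cy3 channel alone called 4077.

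In glucose, a medium that represses the alcA promoter, alcAypkA had lower levels of most alc genes, of some regulators of conidiation, of a siderophore transporter and of penicillin cluster genes. These values average 16 h and 24 h. Among genes with low ratios were tmpA (-3.21 ± 0.15, SE, n = 4 arrays, adjusted p = 3.2e-05), a gene of conidiation signalling, and afeA (-2.91 ± 0.16). akuA, the Ku70 homologue of DNA end joining, was not well above background in alcAypkA on any glucose array and was at least 7.07-fold lower (adjusted p = 0.00056). mirB, a siderophore transporter, stood at -2.48, agd3 and gtb3, which carry names of galactosaminogalactan synthesis, at -2.12 and -1.78, ugd2 at -2.01 with alcAypkA above background on 2 of 4 arrays, and aspf34 at -1.68. Among those with high ratios were admA (2.41 ± 0.09, adjusted p = 2.2e-05), fhpA (1.97), fmaG (1.87), sC (1.77 ± 0.11), exgO (1.58), the zinc transporter zrfA (1.33), the trehalase gene treA (1.24) and hmgA (1.22). thiA was saturated in alcAypkA on every array, so no ratio is given for it in glucose.

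The alc regulon fell in 7 of 10 members in glucose and rose in 2, the same numbers as adjusted over the list alone (camera adjusted p = 0.023, and adjusted p = 0.82 with an estimated correlation). These members include creA and creB. The log2 level of creA was 11.2 in alcAypkA against 11.5 in Wt at 16 h, and 11.4 against 12.2 at 24 h. That of creB was 8.77 against 7.84, and 8.56 against 7.97. AN2286, entered as alcC, had saturated spots. AN0554 stood at -1.92 ± 0.16, AN8979 at -1.91 ± 0.17 (not called at 16 h alone, with -0.73 and adjusted p = 0.087), AN8980 (entered as alcM) at -1.49 and AN8978 (entered as the activator alcR) at -0.77 with alcAypkA above background on 3 of 4 arrays. From 16 h to 24 h in glucose the Wt level rose by 2.97 for AN8979, 1.65 for AN8980, 1.46 for AN0554 and 1.25 for AN8981. In alcAypkA these levels changed by 0.61, -0.020, -0.75 and 0.33, so the averages mix unlike times. Of 22 conidiation genes 6 fell and 16 were not called (6 adjusted over the list alone, camera adjusted p = 0.023, and adjusted p = 0.92 with an estimated correlation). They include flbB (-0.95) and flbD (-0.79), transcription factors upstream of conidiophore development, fluG (-0.53) and laeA (-0.84), a regulator of secondary metabolism. Among other secondary metabolite clusters 7 of 20 members fell and 2 rose (7 and 3 adjusted over the list alone), and camera did not call the list (adjusted p = 0.59). The penicillin genes AN2622 (entered as ipnA, -2.27) and AN2623 (entered as aatA, -1.74) and AN2549 (entered as easD of emericellamide synthesis, -2.65) were among those that fell, with AN2622 above background in alcAypkA on 1 of 4 arrays.

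Further lists had called members in glucose, but camera called none of these lists (adjusted p from 0.10 to 0.68). Their counts are to be read against the 990 genes that rose and 1168 that fell among all 8996. Of 8 siderophore and iron genes 3 fell (3 fell and 1 rose adjusted over the list alone), among them sidI (-1.04) and mirC (-0.84). Of 33 cell wall enzymes 4 rose and 7 fell (5 and 9 adjusted over the list alone), with ags1, an alpha-1,3-glucan synthase, at -1.31, eng2 at -0.71 and cwh41 at 0.94. AN8444, entered as the cell wall synthase celA, stood at -2.70. Of 15 nitrogen and amino acid breakdown genes 3 rose and 4 fell (3 and 4 adjusted over the list alone), with gatA at -1.82, cpcA, the transcription factor of cross-pathway control, at -1.45, crnA at -1.09 and the nitrite reductase gene niiA at 0.92. Of 15 chaperone genes 2 rose and 4 fell (3 and 4 adjusted over the list alone), with wos2 at -1.03, hsp70 at -0.77, hsp90 at -0.74 and the endoplasmic reticulum chaperone bipA at 0.53. Of 13 ribosomal protein and translation genes 4 rose (4 adjusted over the list alone), among them rpL3 (0.79) and rps0 (0.63). Of 10 genes of acetate use and the tricarboxylic acid cycle 4 fell (5 fell and 1 rose adjusted over the list alone), with AN6653 (entered as acuE, malate synthase) at -1.28 and AN5626 (entered as facA, acetyl-CoA synthetase) at -0.73. In the list of ergosterol synthesis 1 of 5 rose (1 adjusted over the list alone). This was hmgA, whose symbol stands for homogentisate dioxygenase of phenylalanine breakdown, an enzyme outside sterol synthesis. In all 2158 of 8996 genes were called in glucose, 990 higher and 1168 lower. Fitted to the glucose arrays alone the comparison called 1199 genes, and with each array left out in turn 1104 (without glucose 16 h replicate 2) to 2471. Median centring in place of loess called 1236, 375 higher and 861 lower.

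**Figure D2:**
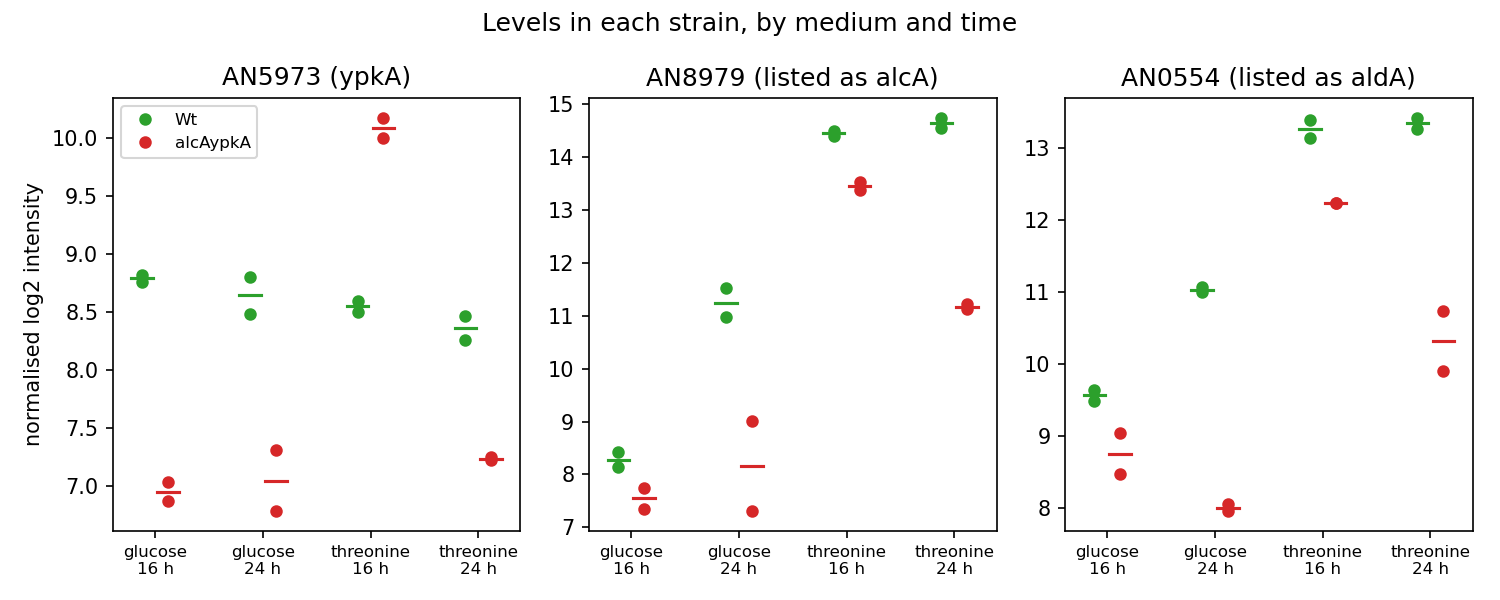
Normalised log2 intensity of ypkA (AN5973), AN8979 (entered as alcA) and AN0554 (entered as aldA) in Wt (green) and alcAypkA (red) on each array (points) with the mean of the condition (lines). The mean of AN8979 in Wt was 8.28 at glucose 16 h, 11.2 at glucose 24 h, 14.4 at threonine 16 h and 14.6 at threonine 24 h, and in alcAypkA 7.55, 8.16, 13.5 and 11.2.

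In threonine, alcAypkA had higher levels of nitrate and proline uptake genes and of thiA, and lower levels of some ribosome biogenesis genes, of most alc genes and of genes of the emericellamide cluster. This comparison averages threonine 16 h, where ypkA was higher than in Wt, with the arrays labelled threonine 24 h, where it was lower. thiA, with its alcAypkA spots saturated on every array, was at least 28.5-fold higher (adjusted p = 5.0e-07). argB, ornithine carbamoyltransferase of arginine synthesis, stood at 1.55 ± 0.13 (SE, n = 4 arrays, adjusted p = 0.00058), hemA, 5-aminolevulinate synthase of haem synthesis, at 1.43, the chitinase gene chiA1 at 1.38 and phoC at 1.37. Among genes with low ratios were akuA (-3.07 ± 0.29, with alcAypkA above background on 1 of 4 arrays), ivoB (-2.85 ± 0.15, 3 of 4 arrays), dewA (-2.33 ± 0.14), the dipeptidyl peptidase genes dppV (-2.18) and dppIV (-1.15), cwc21 (-1.29, 3 of 4 arrays), the catalase gene fgaCat (-1.27) and aspf2 (-1.15).

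Of 25 ribosome biogenesis genes 12 fell in threonine and 13 were not called (14 fell adjusted over the list alone, camera adjusted p = 1.1e-05, and adjusted p = 0.57 with an estimated correlation). spb1 stood at -1.13 ± 0.10, drs1 at -0.97, cbf5 at -0.72 and spb4 at -0.42. The alc regulon fell in 7 of 10 members (7 adjusted over the list alone, camera adjusted p = 0.00028, and adjusted p = 0.31 with an estimated correlation), with AN8980 at -2.32, AN8979 at -2.23 ± 0.17, AN0554 at -2.02 and AN8981 at -1.78. Of 15 genes of nitrogen and amino acid breakdown 8 rose and 7 were not called (8 adjusted over the list alone, camera adjusted p = 0.00073, and adjusted p = 0.57 with an estimated correlation). They include the nitrate genes crnA (1.15), niaD (1.01) and niiA (1.00), the proline transporter prnB (1.07) and AN7463, entered as the ammonium transporter meaA (0.86). Among other secondary metabolite clusters 10 of 20 fell and 2 rose (10 and 2 adjusted over the list alone, camera adjusted p = 0.018, and adjusted p = 0.57 with an estimated correlation). Those entered as emericellamide genes stood at -2.84 (AN2549), -2.59 (AN2548), -1.80 (AN2545) and -1.42 (AN2547).

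Conidiation genes fell in 6 of 22 cases in threonine (6 fell and 1 rose adjusted over the list alone) and camera did not call the list (adjusted p = 0.056). brlA, the central activator of conidiophore formation, was not well above background in alcAypkA and was at least 1.38-fold lower (adjusted p = 0.0073), and ivoA stood at -0.81. Of 8 siderophore and iron genes 3 fell and 1 rose (3 and 1 adjusted over the list alone), with mirB at -1.84, sidD at -1.35 and sidI at -1.09 (camera adjusted p = 0.12). Of 23 amino acid synthesis genes 7 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.13), with metG at 0.69, trpB at 0.65 and trpC at 0.49. In the list of strain marker genes 3 of 5 rose (3 adjusted over the list alone, camera adjusted p = 0.12): argB, pyroA (0.67) and riboB (0.34). Of 10 glycolysis genes 2 rose (2 adjusted over the list alone), with gpdA at 0.96, and of 10 genes of acetate use and the tricarboxylic acid cycle 3 fell (3 adjusted over the list alone), with AN5626 at -1.07 and AN6279 (entered as acuJ) at -0.73. In all 1957 genes were called in threonine, 944 higher and 1013 lower. Fitted to the threonine arrays alone the comparison called 2362 genes, and leaving out single arrays gave 598 (without threonine 16 h replicate 2) to 2651. Median centring called 795, 284 higher and 511 lower, and a stricter filter 1195.

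The strain effect differed between media for some ribosome biogenesis, nitrogen and conidiation genes, a comparison in which a dye effect of a probe cancels. It asks whether the strain effect depends on the carbon source, and the threonine side again includes the arrays labelled threonine 24 h. Ratios were higher in threonine than in glucose for tmpA (2.88 ± 0.21, SE, adjusted p = 0.00040), afeA (2.31), crnA (2.25), cpcA (2.23), gatA (2.21), ags1 (1.66), pyroA (1.55) and argB (1.47). They were lower for exgO (-2.46 ± 0.25, adjusted p = 0.0012), ivoB (-2.43), aspf2 (-2.17), sC (-2.13), dewA (-2.09), fgaCat (-2.09) and fmaG (-1.89). The glucose ratio of dewA rests on weak signal, since Wt was not well above background on most glucose arrays. No difference is given for thiA, which was saturated in alcAypkA.

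Of 25 ribosome biogenesis genes 9 had lower ratios in threonine than in glucose (13 adjusted over the list alone), with spb1 at -1.28, loc1 at -1.20 and cbf5 at -1.02 (camera adjusted p = 1.5e-05, and adjusted p = 0.92 with an estimated correlation). Of 13 ribosomal protein and translation genes 3 were lower (3 adjusted over the list alone), with rps0 at -1.20 and rpl17 at -0.85 (camera adjusted p = 0.025, and adjusted p = 0.92 with an estimated correlation). Of 15 nitrogen and amino acid breakdown genes 6 were higher (6 adjusted over the list alone, camera adjusted p = 0.0073, and adjusted p = 0.92 with an estimated correlation). The penicillin gene AN2622 differed by 1.88, the siderophore transporter mirC by 1.01, trpB by 0.96, flbB by 0.89 and fluG by 0.72, while AN8981 of the alc regulon differed by -1.08 and erg20, farnesyl diphosphate synthase, by -0.97. For the alc regulon 1 of 10 ratios was higher and 4 were lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.11), and AN8979 did not pass the test (-0.32 ± 0.24, adjusted p = 0.39). The comparison called 1889 genes, 984 higher and 905 lower. Slide and medium cannot be told apart in it if each slide holds 1 medium, and leaving out single arrays gave 785 (without threonine 16 h replicate 2) to 2393. Median centring called 783, 449 higher and 334 lower.

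**Figure D3:**
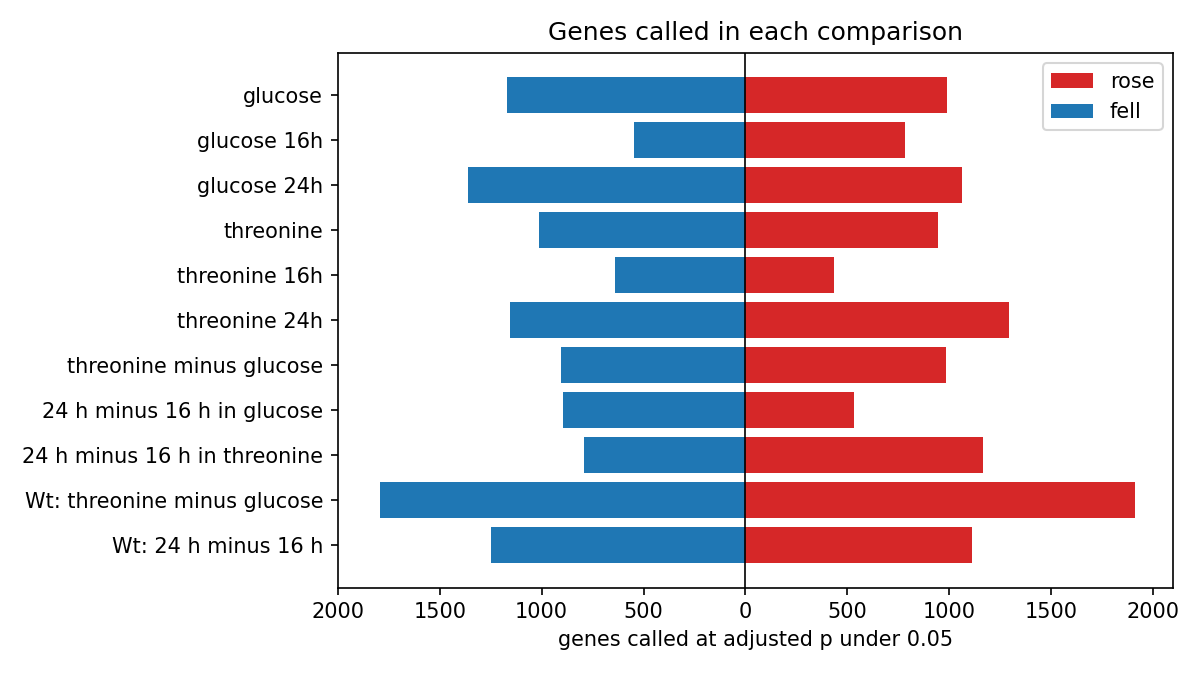
Genes called at adjusted p under 0.05 in each comparison, with those that rose to the right of 0 and those that fell to the left. Rows without a strain compare alcAypkA with Wt, and rows marked Wt compare conditions within Wt. The Wt comparison of media called 3707 genes, and threonine 16 h 1077.

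Taken condition by condition, the effect in glucose included chaperone genes that rose at 16 h and chaperone genes that fell at 24 h, and ribosome biogenesis genes that rose at 24 h, in part of each list. At glucose 16 h admA stood at 3.54 ± 0.13 (SE, n = 2 arrays, adjusted p = 0.00011), pmcC, a vacuolar calcium ATPase, at 3.05 and zrfA at 2.32, while tmpA stood at -3.70 ± 0.21 and afeA at -3.01. Of 15 chaperone genes 5 rose at 16 h (7 adjusted over the list alone, camera adjusted p = 0.00044, and adjusted p = 0.54 with an estimated correlation). At glucose 24 h fmaG stood at 2.53, sC at 2.22 ± 0.16 and aspf2 at 1.91, gatA at -3.65 ± 0.23 and osm1 at -3.33. There 9 of the 15 chaperone genes fell (9 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0032, and adjusted p = 0.51 with an estimated correlation), and 9 of 25 ribosome biogenesis genes rose (9 adjusted over the list alone, camera adjusted p = 0.00043, and adjusted p = 0.61 with an estimated correlation). The change of the ratio from 16 h to 24 h was tested directly. The ratios of 10 of 15 chaperone genes fell (11 adjusted over the list alone, camera adjusted p = 7.8e-07, and adjusted p = 0.23 with an estimated correlation). That of hsp78 changed by -4.12 ± 0.49 (adjusted p = 0.0053). Part of the chaperone genes, hsp78 among them, rose with time in Wt over both media, which can lower these ratios without a fall in alcAypkA. The ratios of osm1 (-4.01) and gatA (-3.66) fell too, and those of rps0 (1.91), aspf2 (1.79) and erg20 (1.52) rose. akuA was at least 7.59-fold lower at 16 h and at least 6.59-fold lower at 24 h.

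At glucose 16 h 1330 genes were called, 781 higher and 549 lower, and at glucose 24 h 2422, 1063 higher and 1359 lower. The change between times called 1429 genes, 534 up and 895 down. Fitted to the glucose arrays alone the counts were 676, 1222 and 427 (74 up and 353 down), and without glucose 16 h replicate 1 they fell to 276 for glucose 16 h and 238 for the change. With median centring the counts were 617 (268 higher and 349 lower), 1113 (311 and 802) and 391 (85 and 306), so the larger direction turned for glucose 16 h.

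At threonine 16 h, the arrays with ypkA above Wt, alcAypkA had lower levels of some ribosome biogenesis and secondary metabolite genes and higher levels of some nitrogen genes. thiA was at least 22.5-fold higher, and hsp78 stood at 2.35 ± 0.35 (SE, n = 2 arrays, adjusted p = 0.0091) and ccpA at 1.89, against akuA at -3.13 (1 of 2 arrays above background), ivoB at -2.07 and dewA at -1.90. Of 25 ribosome biogenesis genes 4 fell (8 adjusted over the list alone, camera adjusted p = 0.00079, and adjusted p = 0.54 with an estimated correlation). Of 15 nitrogen and amino acid breakdown genes 4 rose (6 adjusted over the list alone, camera adjusted p = 0.00097, and adjusted p = 0.51 with an estimated correlation). Among other secondary metabolite clusters 7 of 20 fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.00096, and adjusted p = 0.51 with an estimated correlation).

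On the arrays labelled threonine 24 h, some siderophore, alc and chaperone genes were lower in alcAypkA and some amino acid synthesis genes higher. There thiA was at least 36.1-fold higher, argB stood at 2.53 ± 0.19 (SE, n = 2 arrays, adjusted p = 0.00023) and chiA1 at 2.40, while mirB stood at -4.28 ± 0.32 (adjusted p = 0.00023), ivoB at -3.63 (1 of 2 arrays above background) and akuA was at least 7.68-fold lower. Of 8 siderophore and iron genes 5 fell (6 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.0038, and adjusted p = 0.43 with an estimated correlation). The alc regulon fell in 7 of 10 members (7 adjusted over the list alone, camera adjusted p = 9.5e-05, and adjusted p = 0.23 with an estimated correlation), with AN8979 at -3.47 ± 0.24. Of 15 chaperone genes 7 fell (7 adjusted over the list alone, camera adjusted p = 0.0080, and adjusted p = 0.43 with an estimated correlation). Of 26 genes of mitochondrial respiration and import 7 fell (11 adjusted over the list alone, camera adjusted p = 0.0075, and adjusted p = 0.58 with an estimated correlation). Of 23 amino acid synthesis genes 10 rose and 4 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.041, and adjusted p = 0.58 with an estimated correlation). Tested as a change from 16 h to the arrays labelled 24 h, the ratio of mirB changed by -4.89 ± 0.45 (adjusted p = 0.00096), that of the hydrophobin gene rodA by -3.94 and that of ccpA by -3.71, while those of pst2 (2.75), cpcA (2.24) and dspC (2.13) rose. In that change the ratios of 5 of 8 siderophore and iron genes fell (7 adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.27 with an estimated correlation). So did the ratios of 8 of 26 mitochondrial genes (8 adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.49 with an estimated correlation).

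At threonine 16 h 1077 genes were called, 435 higher and 642 lower, and on the arrays labelled threonine 24 h 2450, 1295 higher and 1155 lower. The change between them called 1954, 1163 up and 791 down. Fitted to the threonine arrays alone the counts were 1259, 2894 and 2358. Without threonine 16 h replicate 1 they fell to 71 for threonine 16 h and 432 for the change, and without threonine 24 h replicate 2 the arrays labelled threonine 24 h called 647 (415 and 232). Median centring called 426 (147 higher and 279 lower), 1011 (480 and 531) and 707 (411 and 296), so the larger direction turned for the arrays labelled threonine 24 h.

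**Figure D4:**
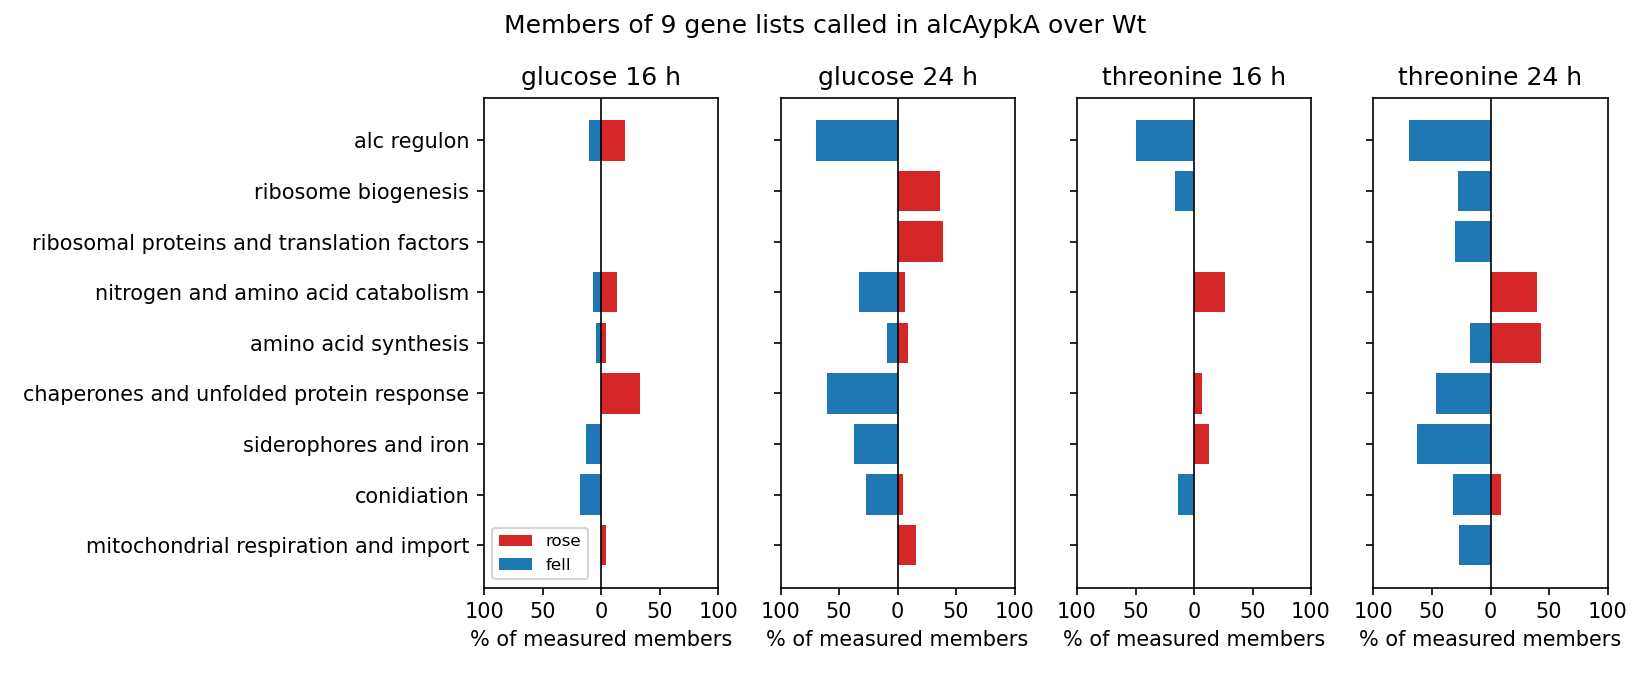
Percent of the measured members of 9 gene lists that rose (right) or fell (left) in alcAypkA over Wt, in each condition. For chaperones and unfolded protein response 5 of 15 members rose at glucose 16 h and 9 fell at glucose 24 h, and for ribosome biogenesis 9 of 25 rose at glucose 24 h and 7 fell on the arrays labelled threonine 24 h.

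Lists of called genes were compared between conditions. Of the genes that rose, 210 were shared by glucose 16 h (781) and threonine 16 h (435), where 37.8 would be shared by independent lists, and 163 genes fell in both against 39.2. Between times, 233 genes rose at both glucose 16 h and glucose 24 h against 92.3 expected, 299 fell at both against 82.9, and 203 fell at both threonine 16 h and the arrays labelled threonine 24 h against 82.4, while 130 fell at threonine 16 h and rose on those arrays against 92.4. At 24 h, 176 genes rose in both media against 153 expected and 279 fell in both against 174, while 215 rose in glucose and fell on the arrays labelled threonine 24 h against 136, and 260 fell in glucose and rose there against 196. The mean log ratios of 2 conditions correlated across genes at 0.42 between media at 16 h and at 0.36 between times in glucose, and at -0.02 to 0.07 for the other pairs of conditions. The rank correlations were 0.40 between media at 16 h, 0.15 between times in glucose and -0.08 to 0.03 for the others. Genes are not independent replicates, and a dye effect of a probe adds to every overlap in the same direction. The fit also used 1 estimate of the spread of a gene for all conditions. A gene of small spread is therefore called more readily in each condition, which adds to overlaps in the same and in opposite directions. The numbers for independent lists are thus too low a standard. In all 4 conditions 11 genes rose, among them thiA and phoC, and 38 fell, among them akuA, dppIV and cwc21, where independent lists would share 0.64 and 0.76. Over the 9 comparisons of strains camera called 56 of 252 list tests, and over both Wt comparisons 22 of 56. With an estimated correlation 0 of these held, while 16 and 3 list tests had an unadjusted p under 0.05, the lowest adjusted p was 0.23 and 0.45, and fry called 40 of the 56 and each of the 22.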

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

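Tests of stretches of the genome, of exchanged channels, of RNA from glucose cultures, of lower alc activity and of dim Cy5 signal were chosen after the results they bear on were seen. The other tests of explanations were chosen before.

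The strain effect differed between media, by limma's test of the difference, for many named genes that were called in at least 1 medium. Log2 differences, threonine minus glucose, are given, and the threonine side includes the arrays labelled threonine 24 h. For the targeted gene ypkA (AN5973) it was 1.92. Differences above 0 were found for tmpA (2.88), afeA (2.31), crnA (2.25), cpcA (2.23), gatA (2.21), AN2622 (1.88), ags1 (1.66), pyroA (1.55), argB (1.47), aspf34 (1.25) and gtb3 (1.21). They were also found for AN2623 (1.13), AN8444 (1.12), agd3 (1.08), mirC (1.01), AN6653 (1.00), trpB (0.96), hemA (0.94), AN7463 (0.93), AN2621 (0.92) and flbB (0.89). Smaller ones were those of chiA1 (0.82), gpdA (0.76), wos2 (0.74), fluG (0.72), trpC (0.69), flbD (0.55) and riboB (0.50).

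Differences below 0 between media were found for exgO (-2.46), ivoB (-2.43), admA (-2.23), aspf2 (-2.17), sC (-2.13), dewA (-2.09, with Wt not well above background on most glucose arrays), fgaCat (-2.09), fmaG (-1.89), dppV (-1.79), AN2548 (-1.38), spb1 (-1.28) and fhpA (-1.21). They were also found for rps0 (-1.20), loc1 (-1.20), AN8981 (-1.08), cbf5 (-1.02), sidD (-1.02), drs1 (-0.99), cwh41 (-0.99), AN2547 (-0.99) and AN8980 (-0.83). Smaller ones were those of bipA (-0.75), rpL3 (-0.69), pdiA (-0.66), cwc21 (-0.65) and spb4 (-0.61). By camera's test 3 lists differed, with median log2 differences of 0.39 for nitrogen and amino acid breakdown, -0.39 for ribosomal proteins and translation factors and -0.46 for ribosome biogenesis. Each of these had adjusted p = 0.92 with an estimated correlation.

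The strain effect differed between 16 h and 24 h, by the same test. In glucose the change was -4.01 for osm1, -3.66 for gatA, -3.19 for pmcC, -2.26 for admA, -1.99 for zrfA, 0.90 for sC and 1.79 for aspf2. In threonine, toward the arrays labelled threonine 24 h, it was -4.89 for mirB, -3.71 for ccpA, -2.83 for hsp78, -2.66 for ypkA (AN5973), -1.56 for ivoB, 1.96 for argB and 2.04 for chiA1.

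ypkA (AN5973) was lower in alcAypkA than in Wt on the arrays labelled threonine 24 h, against an induced promoter. Had RNA of glucose cultures been used there, AN8979 (entered as alcA) would have lain near its glucose level. It was 3.39 higher in Wt than at glucose 24 h, which argues against that for the Wt samples. In alcAypkA its mean log2 level was 11.2, against 8.16 at glucose 24 h, so it lay above its glucose level there too. Of 101 genes called in 1 direction in the other 3 conditions, 65.3% had that sign there. This share lay between the bounds set for either answer, so it does not decide whether the channels were exchanged. Its exact 95% interval (55.2 to 74.5%) takes genes as independent, which they are not. Against exchanged channels, akuA and thiA kept their directions (at least 7.68-fold lower and at least 36.1-fold higher). An exchange would also put Wt at log2 levels of 7.25 and 7.22 for ypkA, against 8.48 to 8.82 on the other Wt arrays. For AN8979 it would put Wt at 11.2, against 14.4 at threonine 16 h. An exchange is not excluded, since a dye effect of a probe keeps its sign under it and was not measured, and since the levels of Wt at that time are known from these arrays alone. Lower activity of the alc genes in alcAypkA at 24 h, a biological explanation, may account for the pattern if the channel labels are right. In threonine AN8979 changed by -2.28 from 16 h to 24 h in alcAypkA and by 0.20 in Wt. The 2 genes did not go together at threonine 16 h, however. There AN8979 was lower in alcAypkA than in Wt (13.5 against 14.4), while ypkA was higher (10.1 against 8.55). This explanation stays open.

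In all 4 conditions 49 genes moved the same way, 11 up and 38 down. Removing from each array the trend of the log ratio with the base composition and brightness of the probe kept 98.5% of their median size (1.41 before and 1.38 after, with 48 of 49 still called), but the trend explained 0.33% of the variance and moved other genes by a median of 0.015, so this decides nothing and that dye bias stays open. Dye bias of single probes cannot be told apart from a strain effect without a dye swap; the log2 ratio shared by conditions had a standard deviation of 0.243 between probes. Of 45 placed genes 4 had another of the set within 5 genes, where random sets had a median of 2 and a 95th percentile of 6, so stretches of the genome that differ between the strains stay open. The 49 genes did not follow the direction of ypkA, which was above Wt at threonine 16 h and below it in the other conditions. Among them akuA was well above background on 8 arrays in Wt and on 1 in alcAypkA. The named difference of the strains stays an open, untested biological explanation. Other differences between the strains were not tested and stay open too.

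More genes were called at 24 h than at 16 h in both media. Scale normalisation turned this in glucose (2060 at 16 h and 1946 at 24 h), but it makes the spread of the arrays equal and so removes a wider spread at 24 h. In threonine leaving out 24 h replicate 2 turned it and leaving out 24 h replicate 1 did not. In both of these fits the 24 h condition has 1 array, so its count is not on the same footing as that of 16 h. Dim Cy5 signal on replicate 1 of both 24 h conditions does not account for the larger counts at 24 h: on the replicate 2 arrays the standard deviation of the log ratios was 1.28 times that of 16 h in glucose and 1.55 times in threonine (6044 genes). A lag of alcAypkA behind Wt stays open: the log ratio at 24 h correlated across genes with the change of Wt from 16 h to 24 h, taken from the other replicate, at -0.49 in glucose and -0.23 in threonine, and at 16 h at 0.25 and 0.17. The level of Wt enters both sides of each correlation and can give these signs without a lag, so they do not speak for one. Time as a cause in its own right was not tested apart from this.

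The 8 arrays can be split into 4 and 4 in 35 ways, and each split was fitted on its own, without the other factor, so its counts lie below those of the full fit. For threonine minus glucose 2 of the splits called as many genes as the real one (167), so chance is not excluded by this count; the other was the split by time, with 446, and splits by neither medium nor time called at most 5. For Wt threonine minus glucose the real split called 1421 genes and the highest other 108, so no other split reached it (1 of 35 splits). This is the lowest share the test can give. Splits by neither medium nor time called 0, but they put both differences into the spread within their groups. The count alone therefore does not exclude chance, and it cannot separate medium from slide. For Wt 24 h minus 16 h the real split called 108, and 2 splits were as large, the other being the split by medium with 1421. That split points to the structure of the samples by medium, or by slide if each slide holds 1 medium.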

How the results depend on the processing

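Leaving out both arrays with a dim Cy5 channel, the crossed replicate pairing and, for the gene lists, leaving out single arrays, no background correction, processed signals and scale normalisation were chosen after seeing the data. The ypkA ratio in glucose kept its direction and side of the threshold under each alternative (-3.13 to -1.51). In threonine it was -0.060 with processed signals, -0.060 with the deposited ratios and 0.43 and called with scale normalisation. Of 252 list tests camera called 50 to 57 under other normalisations and 0 with an estimated correlation, where 16 had an unadjusted p under 0.05 and fry called 67. With median centring 43 of the 56 main calls were kept in the same direction.

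Counts of called genes moved by over 1.5 times as follows, and the cause was not tested unless stated. A 2-fold minimum, which asks for more by construction, left 561 in glucose, 639 at glucose 16 h, 956 at glucose 24 h, 384 in threonine, 475 at threonine 16 h, 983 at threonine 24 h, 770 for threonine minus glucose, 1292 for 24 h minus 16 h in threonine, 373 for Wt 24 h minus 16 h (306 higher and 67 lower) and 653 for Wt threonine minus glucose. Median centring gave 1236 in glucose, 617 at glucose 16 h, 1113 at glucose 24 h, 795 in threonine, 426 at threonine 16 h, 1011 at threonine 24 h, 783 for threonine minus glucose, and 391 and 707 for 24 h minus 16 h in glucose and threonine. Fits to glucose alone gave 1199 in glucose, 676 at 16 h, 1222 at 24 h and 427 for 24 h minus 16 h. They use fewer arrays, but so does the fit to threonine alone, which called 2362 in threonine against 1957 in the full fit. Scale normalisation gave 2060 at glucose 16 h (1946 at 24 h) and 2162 at threonine 16 h. The stricter filter, with 6044 genes tested, gave 1195 in threonine and 586 at threonine 16 h. Without both arrays of dim Cy5 signal 2412 were called at glucose 16 h, 2114 at threonine 16 h, and 2500 and 3007 for 24 h minus 16 h in glucose and threonine. The Cy3 channel alone gave 4077 for Wt 24 h minus 16 h.

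With each array left out in turn, the lone array of a condition was assumed to vary like the other conditions. Glucose called 1104 to 2471 genes (1104 without glucose 16 h replicate 2, 1141 without replicate 1). Glucose 16 h called 276 (without its replicate 1) to 1840, with 381 without its replicate 2 and 872 without either threonine 16 h array. Glucose 24 h called 1761 to 2312. Threonine called 598 (without threonine 16 h replicate 2) to 2651, with 654 without replicate 1 and 1026 without threonine 24 h replicate 2. Threonine 16 h called 71 (without its replicate 1) to 1563, with 75 without its replicate 2. Threonine 24 h called 647 (without its replicate 2) to 3218. Threonine minus glucose called 785 (without threonine 16 h replicate 2) to 2393, with 910 without replicate 1, 1076 and 978 without glucose 16 h replicates 1 and 2, and 1196 without threonine 24 h replicate 2. The change from 16 h to 24 h in glucose called 238 (without glucose 16 h replicate 1) to 1777, with 492 without replicate 2 and 744 without either threonine 16 h array. In threonine it called 432 (without threonine 16 h replicate 1) to 2681, with 488 without replicate 2 and 618 without threonine 24 h replicate 2. Wt 24 h minus 16 h called 936 (without threonine 16 h replicate 2) to 2981, with 1289 without replicate 1, 1533 and 1182 without glucose 16 h replicates 1 and 2, and 1315 without threonine 24 h replicate 2. Wt threonine minus glucose called 2350 (without threonine 16 h replicate 2) to 4286. The list tests called were 52 to 65 of 252, and ypkA lay between -1.93 and -1.51 in glucose and between 0.14 and 0.27 in threonine. The upper counts of 1840, 2651, 1563, 3218, 2393, 2681, 2981 and 4286 were without glucose 24 h replicate 1.

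Arrays of the same number did not pair in a common way: deviations of glucose and threonine at 16 h correlated at -0.59 and those at 24 h at 0.37. The other pairs of conditions lay between -0.12 and 0.059. A replicate block called 1936 genes in glucose, 1189 at glucose 16 h, 2192 at glucose 24 h, 1743 in threonine, 865 at threonine 16 h, 2218 at threonine 24 h, 1635 for threonine minus glucose, 1171 and 1716 for 24 h minus 16 h in glucose and threonine, 2269 for Wt 24 h minus 16 h and 3634 for Wt threonine minus glucose, each within 1.5 times of the count without it. The crossed pairing called 1462 and 1904 for 24 h minus 16 h in glucose and threonine. The ypkA ratio in threonine, whose sign turned with processed signals and with the deposited ratios, is not part of the next count. Of 1993 values of named genes under the other settings 1938 kept direction and side of the threshold, 53 lost the call, 26 of them with median centring, and 2 gained it. Of 1624 with an array left out 1540 kept both, 83 lost the call and 1 gained it. The brightest probe per gene was not run, with 1 probe per gene. Signal over background limits the 2147 genes left out and ratios of genes dim in 1 strain.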

Other observations

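The test of a smaller response to the medium was chosen before its result was seen.

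Camera called several gene lists in single conditions beyond the calls described above. At glucose 24 h 3 of 5 genes of cell wall synthesis fell (3 adjusted over the list alone, camera adjusted p = 0.024, and adjusted p = 0.61 with an estimated correlation). There 6 of 22 conidiation genes fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.024, and adjusted p = 0.61 with an estimated correlation), and 5 of 13 ribosomal protein and translation genes rose (5 adjusted over the list alone, camera adjusted p = 0.0032, and adjusted p = 0.61 with an estimated correlation). On the arrays labelled threonine 24 h 4 of 14 genes of the sterigmatocystin cluster fell and 2 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.016, and adjusted p = 0.43 with an estimated correlation). There 5 of 11 genes of polarity, actin and endocytosis fell (5 adjusted over the list alone, camera adjusted p = 0.023, and adjusted p = 0.43 with an estimated correlation), and 9 of 33 cell wall enzymes fell and 1 rose (10 and 1 adjusted over the list alone, camera adjusted p = 0.016, and adjusted p = 0.43 with an estimated correlation).

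In glucose AN8979, entered as alcA and followed by condition after its values were seen, had a mean log2 level of 8.28 in Wt at 16 h and 11.2 at 24 h, and of 7.55 and 8.16 in alcAypkA. Its ratio was -0.73 at 16 h (limma adjusted p = 0.087) and -3.09 ± 0.24 at 24 h (SE, n = 2 arrays, adjusted p = 0.00030), and the change between times was -2.36 ± 0.34 (adjusted p = 0.0075). In threonine the change was -2.48 ± 0.34 toward the arrays labelled threonine 24 h (adjusted p = 0.0040).

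A smaller response to the medium in alcAypkA than in Wt was the hypothesis, and the measured response was larger. This does not decide the question. On every array alcAypkA was labelled with Cy5, and a wider range of signal in that channel would give the same result. Genes whose mean over both strains changed by at least 2-fold between media were picked on 1 replicate and measured on the other. The median change in alcAypkA was 134% of that in Wt over 510 genes and 129% over 574 genes, with the replicates exchanged. Over all genes, 3341 were called between media in alcAypkA and 3707 in Wt, and at a 2-fold minimum 822 and 653. The threonine arrays here include those labelled threonine 24 h.

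The 10 spike-in control probes, which were not used in the normalisation, had mean log2 ratios of -0.41 and -0.07 at glucose 16 h, 0.84 and -0.78 at glucose 24 h, -0.25 and -0.25 at threonine 16 h, and -0.05 and -0.44 on the arrays labelled threonine 24 h.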
